A study of Mus musculus with 5 samples.

How the data were processed

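Total RNA from 5 mouse cultures was hybridised to single-colour arrays, with 1 array for each group: ESCs at day 0, control and Linc1405 knockdown cells at day 4, and control and Linc1405 knockdown cells at day 10. Groups were taken from the labels, which call the day 4 cells mesoderm and the day 10 cells cardiomyocytes. The labels describe the modified line as a knockdown of Linc1405 and name its samples MES_1405KIpA and CM_1405KIpA, names whose meaning is not given in the sources used here. Per the labels' protocols, ESCs grew with 15% serum and leukaemia inhibitory factor at 1000 U/ml on feeder cells, which were removed at harvest. Day 4 cells received Bmp4 at 0.2 ng/ml with Activin A and VEGF at 5 ng/ml each, and day 10 cells received bFGF at 10, VEGF at 5 and FGF10 at 25 ng/ml. Per the same protocols, 5 µg of amplified RNA labelled with Cy5 was made for hybridisation.

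The deposited values were probe intensities on a linear scale. The submitters' processing notes name Agilent Feature Extraction 10.7.1.1, and any normalization by the authors is not given in the sources used here. Some deposited intensities were at or below 0 (3 probes for ESCs, 38 and 0 for control and knockdown at day 4, 3 and 1050 for control and knockdown at day 10), so a background had been subtracted. The 5 arrays had different medians, from 344 to 745, and different 75th percentiles, from 2683.5 to 5007, so the values were not normalized between arrays. The design had provided for quantile normalization in that case, and the values as deposited then became an alternative. Detection calls and saturation marks were not used here.

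Intensities were quantile normalized over the 5 arrays on the linear scale, set to a floor of 100 and converted to log2 values. The floor took 19.0 to 19.1% of the probes of each array, and a difference with an array at the floor is given as a bound. Of 26423 probes, 20377 carried 1 gene symbol, 0 carried several and 6046 were unnamed here. Symbols were updated through a gene table of the assembly GRCm38.p6, which served only for names and for which genes neighbour each other. In this way 18213 probes were named by current symbol and 2126 through a synonym, and 38 kept their older symbol. The brightest probe over the 5 arrays stood for each of 17742 genes, of which 2278 had more than 1 probe, and disagreement in sign between probes is stated where such a gene is named. Unnamed here were several heart genes, among them Myh6, Myh7, Myl2, Myl7 and Nkx2-5.

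Log2 differences were taken between pairs of arrays: knockdown minus control at day 4 and at day 10, control day 4 minus ESCs, and control day 10 minus control day 4. A gene was counted where its brighter array was at or above the 50th percentile (a log2 intensity of 9.16) and the difference was at least 2-fold. With 1 array per group there was no spread within a group, and no p-value was computed, and the number of arrays limits the precision. The between-probe SD was the SD, over pairs of probes of the same gene, of how far their log2 differences lay apart, divided by the square root of 2 so that it applies to a single probe, and it covers probe error and not differences between cultures. For gene lists, the median log2 difference of all measured members was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list was said to lie outside the random range at or below percentile 2.5 or at or above 97.5. Members of a list can vary together, so the percentile describes these arrays and is not a p-value.

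The comparisons, the thresholds, 38 lists with 720 genes, 34 anchor genes and the rule for named genes were fixed before the data were examined. Of the list genes 608 were measured, and 37 lists had at least 5 measured members. The lists covered stages from pluripotency to heart muscle, other cell types that the cultures could hold, signalling pathways, chromatin complexes and general cell states, and some genes belong to more than 1 list. Named genes were the 10 highest and 10 lowest differences past the filter with both arrays above the floor, leaving out gene models and clones, up to 4 members of a list in the direction of its median and 2 against it, and the anchor genes, of which 26 were measured. Genes named outside that rule are examples from counts of shared genes or from lists chosen later.

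Time courses were compared across genes by Pearson r and the ratio of SDs. Overlaps were set beside the number that independent lists would share. Sets of genes that separate stages in control cells were evaluated only on arrays not used to choose them, beside 1000 random sets. Alternatives were the values as deposited, loess centring of each pair (span 0.3, 3 iterations), no filter, a filter at the 75th percentile, a 4-fold threshold, the mean of all probes of a gene and list members past the filter only. Floors of 50 and 200 and scaling to a common 75th percentile were added after seeing the data. Under settings without equal medians, list and gene differences were taken relative to the median of all genes. Counts of 2-fold genes were not centred in this way.

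The computation was tested on simulated data for 17742 genes with the between-probe SD as noise. For knockdown against control at day 4, 100 of 100 genes changed by 1.5 on the log2 scale were recovered and 0 of 10382 unchanged genes were counted. For day 10, 97 of 100 such genes were recovered and 4 of 10509 unchanged genes were counted. Genes changed by 3.0 were recovered in 100 of 100 cases in both. The changed genes were planted only among genes well above the filter in the control array. Under the simulated noise the 2-fold limit lay several SDs from 0, so few false counts were bound to follow. Differences between cultures were not simulated, and all genes past the filter had SDs of 0.36 at day 4 and 0.55 at day 10. The simulation therefore checks the computation and gives no error rate for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.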

Results

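Transcript levels were measured on single-colour microarrays in mouse embryonic stem cells (ESCs) and in cells differentiated from them towards heart muscle. The design compared control cells with cells in which Linc1405, a long non-coding RNA, was knocked down, and the series title names a complex of Linc1405 with Eomes, a T-box transcription factor of the primitive streak. Each of the 5 groups held 1 array: ESCs at day 0, control and knockdown cells at day 4 (mesoderm cells in the labels), and control and knockdown cells at day 10 (cardiomyocytes in the labels). Each array gave intensities for 26423 probes, and 20377 of these probes were assigned to 17742 named genes. Median intensities before normalization were 633 for ESCs, 665 and 745 for control and knockdown at day 4, and 344 and 473 for control and knockdown at day 10. With 1 array per group no spread between cultures of a group could be measured and no test was run, so every difference below describes a pair of arrays. As a measure of probe error only, the SD of the log2 difference of a single probe, estimated from pairs of probes of the same gene, was 0.206 for knockdown against control at day 4 (949 genes) and 0.270 at day 10 (986 genes). That SD was 0.621 for control day 4 against ESCs (1016 genes) and 0.752 for control day 10 against control day 4 (1043 genes).

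Linc1405 was not identified among the named probes, so its level was not analysed and the knockdown was not checked here. Whether a Linc1405 probe is among the 6046 probes unnamed here is not known. Eomes was at a log2 intensity of 12.01 in control and 12.17 in knockdown cells at day 4, a difference of 0.16. At day 10 Eomes was at 10.05 in control and 10.31 in knockdown cells, a difference of 0.26. Both Eomes differences were within the between-probe SD. Wdr5, a subunit of histone H3 methyltransferase complexes, differed by -0.02 at day 4 and 0.45 at day 10. Kat2a, a histone acetyltransferase, differed by -0.06 at day 4 and -0.35 at day 10. The list of Eomes, Wdr5 and acetyltransferase partners had median log2 differences of 0.07 at day 4 and 0.08 at day 10, at percentiles 89.4 and 74.5 of matched random lists, and 0 of its members past the intensity filter differed 2-fold on either day.

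The comparison of control day 4 cells with ESCs described entry into mesoderm. Primitive streak genes were higher at day 4: the list median was 2.33, with 12 of 14 members past the filter at least 2-fold higher, among them Evx1 (6.88), Fgf8 (4.43) and T (4.30), the T-box factor brachyury. Early cardiac mesoderm genes had a median of 2.40, with 18 of 21 at least 2-fold higher, including Foxf1 (5.98) and Kdr (5.76), the VEGF receptor of early mesoderm. Mesp1, a transcription factor of cardiac progenitors, was at least 7.13 higher, since the ESC array lay at the intensity floor. Pluripotency genes had a median of -4.23, with 19 of 23 lower, led by Tcl1 (-8.38) and Esrrb (-7.34), and Sox2 differed by -5.91. Eomes was almost level between ESCs and day 4 (-0.14).

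Genes of blood and endothelial progenitors were also higher at day 4, with list medians of 2.70 and 1.27, led by the transcription factors Tal1 (6.73) and Lmo2 (6.32). Definitive endoderm genes had a median of 1.21, including Sox17 (4.19) and Sox7 (at least 4.43), which endothelium also uses. Genes past the filter with both arrays above the floor, leaving out gene models and clones, were ranked by their difference. Other genes among the 10 highest ranked were Asb4 (8.25), Rspo3 (7.02), a Wnt agonist, Cfc1 (6.35), a Nodal coreceptor, Spin2c (6.11) and Vrtn (6.08). Among the 10 lowest ranked stood Mymx (-8.49), Ooep (-8.40), Triml1 (-7.91), Morc1 (-7.63) and Anxa1 (-6.74). Fibroblast and matrix genes had a median of -0.78, with Dcn (-4.86) and Postn (-4.52) lower at day 4, and the labels place the ESCs on feeder cells that were removed before harvest. In all, 1447 genes were at least 2-fold higher and 1574 lower among 11293 past the filter. Of the 37 lists with enough members, 12 lay above and 9 below the central 95% of random lists. Among 37 lists of randomly drawn genes 1.85 would lie outside. Members of the real lists can vary together and lists share genes, so 1.85 is no chance expectation for them. Without normalization between arrays the counts were 2244 higher and 1219 lower, with the median of all genes at 0.36.

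The comparison of control day 10 with control day 4 described the appearance of heart muscle and other mesodermal cells. Sarcomere genes had a median of 4.10, with 13 of 15 members past the filter at least 2-fold higher, led by Actc1 (7.47), cardiac actin, and Ldb3 (5.84), with Smpx at least 6.29 higher. Cardiac hormone and metabolism genes had a median of 1.60, including Nppa (6.19), which encodes atrial natriuretic peptide, and the median was 3.05 with members past the filter only and 2.46 with a floor of 200. Calcium handling and ion channel genes had a median of 1.87, led by Popdc2 (6.91), with Pln, the phospholamban gene, at least 6.28 higher. Among cardiac transcription factors (median 2.03), the cofactor genes Csrp3 (8.39) and Ankrd1 (8.36) showed the highest differences among the ranked genes, while Tbx3 (-4.18) and Hand1 (-2.63) were lower. Primitive streak genes had a median of -2.32, with T (-5.64), Evx1 (-5.01) and Mixl1 (-4.71) lower, and Mesp1 was at least 7.13 lower, at the floor.

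Markers of other cell types stood beside the cardiac genes at day 10. Fibroblast and matrix genes had a median of 4.07, with 21 of 23 at least 2-fold higher, and with Lum and Col3a1, matrix genes at the floor at day 4, at least 9.49 and 7.62 higher. Liver-type endoderm genes had a median of 3.14, with 14 of 18 higher, including Afp (6.99), alpha-fetoprotein. Epicardium genes had a median of 2.69, including Upk1b (6.82) and Upk3b (5.51), and of 4.17 with members past the filter only. Endothelial genes had a median of 1.74, while the blood list stood at -2.16, with Car2 (-5.42) and Gata2 (-4.36) lower. Against that median, the macrophage genes Csf1r and Cd68 were higher, Csf1r by at least 4.98 with its day 4 array at the floor and Cd68 by 2.17. Outside the lists, the 10 highest ranked genes included Plagl1 (8.14), Sh3bgr (7.80), Pgam2 (7.67), Igfbp7 (7.58) and Emp1 (7.02). The lowest ranked genes of this comparison included Fgf3 (-6.53), Lgr5 (-6.06), Alox15 (-5.90), Fosb (-5.81) and Six2 (-5.04). In all, 2182 genes were at least 2-fold higher and 2214 lower among 11436, and cell cycle genes had a median of -1.05. Without normalization between arrays the counts were 1164 higher and 5233 lower, with the median of all genes at -0.88, and with loess centring of the pair they were 2537 and 1714.

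**Figure D1:**
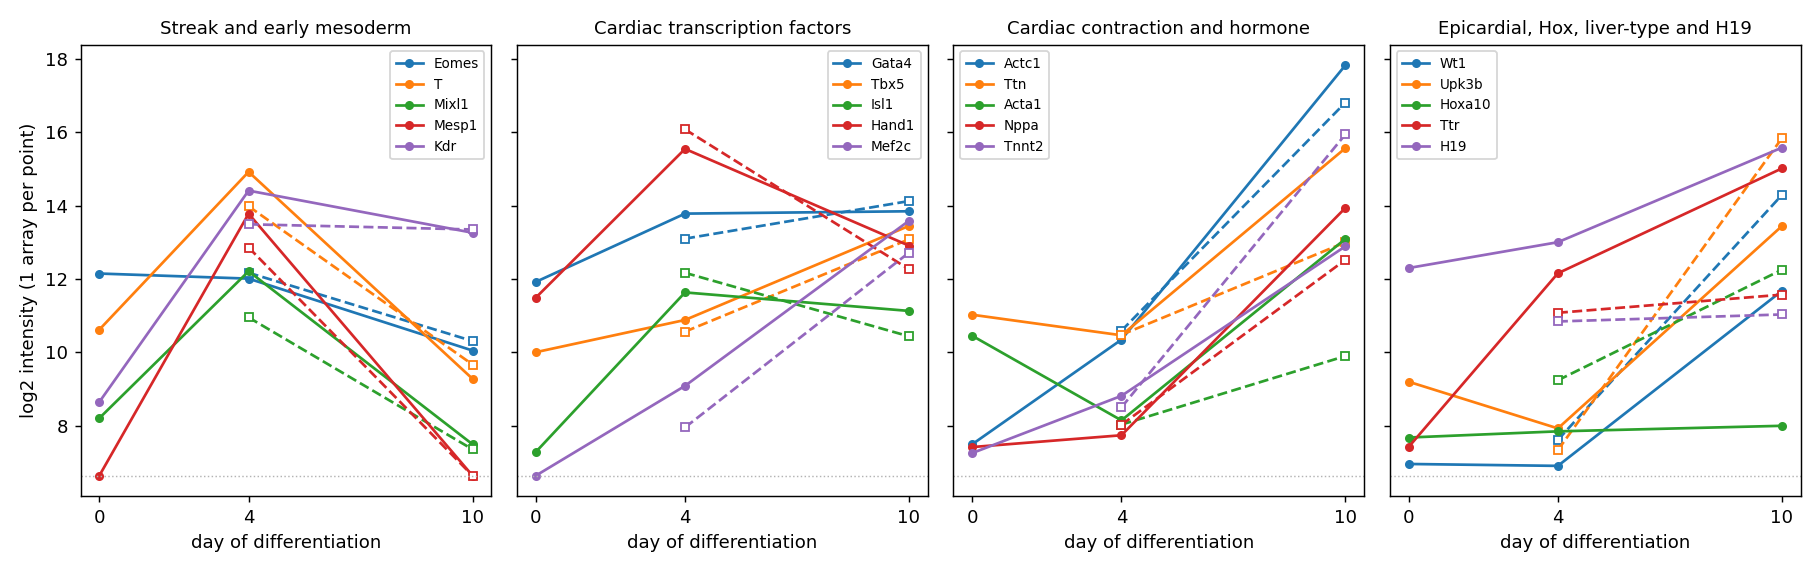
Log2 intensity (vertical axis, 1 array per point) against day of differentiation for 20 genes in 4 panels; filled circles with solid lines are control arrays, open squares with dashed lines are knockdown arrays, and the dotted line is the intensity floor. Actc1, Ttn, Acta1 and Nppa were lower in the knockdown array at day 10, Tnnt2 was higher by 3.05, and Eomes differed by 0.16 at day 4 and 0.26 at day 10.

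Knockdown against control at day 4 compared the lines at the mesoderm stage. Primitive streak and mesendoderm genes were lower as a group in knockdown cells: the list median was -0.86, at percentile 0 of 10000 matched random lists, and 7 of 14 members past the filter were at least 2-fold lower. Sp5 (-2.47), a Wnt target, Foxa2 (-1.68), Mixl1 (-1.26) and Wnt3 (-1.21) led the group, T differed by -0.94 and Gsc by -0.52, and Eomes stood against it at 0.16. Early cardiac mesoderm genes did not stand apart, with a median of 0.03 at percentile 64.6 and only Mesp2 (-1.12) of 21 members at least 2-fold lower. Within that list Mesp1 and Kdr each differed by -0.92, while Hand1 (0.53) and Pdgfra (0.28) lay on the other side.

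Cardiac transcription factors (median -0.01) and sarcomere genes (0.07) lay inside the range of random lists at day 4, with Gata4 at -0.68, Hand2 at -0.61, Tbx5 at -0.32, Gata6 at 0.12 and Isl1 at 0.53. The sarcomere list lay above the range with loess centring (0.12) and with members past the filter only (0.20). Mef2c differed by -1.13 on its brighter probe and -0.76 on the other, but its brighter array lay below the filter. Definitive endoderm genes were lower as a group (median -0.55, 5 of 16 at least 2-fold lower), led by Trh (-2.94), Foxa1 (-1.95), Cldn6 (-1.77) and Spink1 (-1.74), and Sox17 differed by -0.99. Epithelial genes had a median of -0.31, including Crb3 (-1.24), and pluripotency genes -0.35, including Tdgf1 (-3.48), the Nodal coreceptor Cripto, and Tfcp2l1 (-1.15). Endothelial genes had a median of -0.15, including Tie1 (-1.15), and p53 targets -0.16. Liver-type endoderm genes had a median of -0.19, which was 0 and inside the range with a floor of 200, where the median member lay at the floor in both arrays. Paraxial and presomitic mesoderm genes had a median of -0.10, with Dll1 (-1.84) and Dll3 (-1.20) lower but Cdx4 (2.01) and Cdx2 (1.71) higher, and that median came inside the range with members past the filter only (0.0023) and with scaling to the 75th percentile (-0.065).

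Hox genes, which mark position along the body axis, were higher as a group in knockdown cells at day 4. Their list median was 1.01 and 14 of 23 members past the filter were at least 2-fold higher, led by Hoxb8 (2.61), Hoxc9 (2.51), Hoxb6 (2.26) and Hoxd9 (2.20). The highest differences among the ranked genes were those of Tbx4 (3.76, 13.6-fold) and Pitx1 (3.04, 8.22-fold), transcription factors of the hindlimb field. Fyb2 (2.61), Cdk5r1 (2.29) and Itga4 (2.18) followed, and Gtf2ird1 was higher by 2.19 on its brightest probe but by 0.42 and -0.12 on its other probes. Hypoxia and glycolysis genes had a median of 0.29 with 0 of 20 at least 2-fold apart, blood genes 0.23, including Klf1 and Alas2 (1.32 each), FGF pathway genes 0.13 and trophoblast genes 0.15, the last inside the range with scaling to the 75th percentile (0.038). The lowest ranked genes besides Tdgf1 and Trh were Cep57l1 (-4.72), Mmp17 (-3.96), Ovol1 (-3.13), Fgf5 (-2.91), Otx2 (-2.90), Htr3b (-2.63), Fam20c (-2.58) and Clec4e (-2.53). Zeb2, a regulator of epithelial-mesenchymal transition, was left out of this ranking because its knockdown array lay at the floor. It was at 11.04 in control cells, and its difference of -4.40 is a bound. In all, 86 genes were at least 2-fold higher and 157 lower among 10699, and 8 lists lay below and 5 above the random range. Probes of the same gene often disagreed at this day: of 13 genes 2-fold apart on the first of 2 probes, 8 had the same sign on the second. The r between such probes was 0.41 over 949 genes. At day 10, 44 of 48 had the same sign, with an r of 0.69, so single-gene differences at day 4 are the less certain. Without normalization between arrays the split was 123 higher and 114 lower, with a median of all genes of 0.20.

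**Figure D2:**
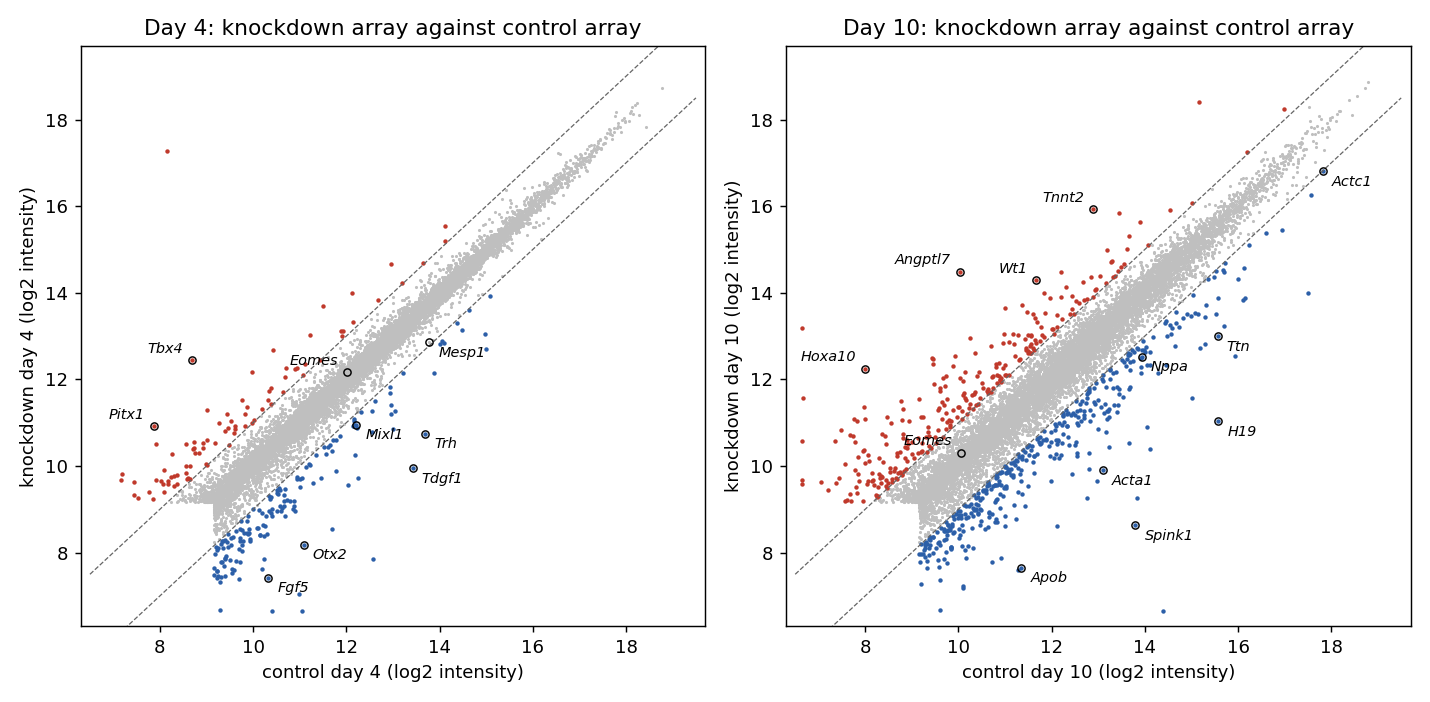
Log2 intensity in the knockdown array (vertical axis) against the control array (horizontal axis) at day 4 and day 10, 1 point per gene past the intensity filter; dashed lines mark 2-fold differences, and red and blue points are genes at least 2-fold higher or lower in the knockdown array. At day 4 the coloured points number 86 and 157, and at day 10 they number 272 and 393.

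Knockdown against control at day 10 compared the lines at the cardiomyocyte stage. Sarcomere genes were lower as a group in knockdown cells, with a median of -1.06 and 10 of 15 members past the filter at least 2-fold lower. Acta1 (-3.19), skeletal actin that fetal heart also expresses, Ttn (-2.57), the titin gene, Actn2 (-2.48) and Ldb3 (-1.94) led, and Actc1 differed by -1.02. Against the group, Tnnt2, cardiac troponin T, was higher by 3.05 on its single probe, and Tpm1 differed by 0.22 on its brightest probe but by -1.80 and -0.07 on its other probes. Cardiac hormone and metabolism genes had a median of -1.20 with 7 of 9 at least 2-fold lower, including Ppargc1a (-2.02), Cox7a1 (-1.96), Mb (-1.59), myoglobin, and Nppa (-1.41).

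Cardiac transcription factors and cofactors had a median of -0.64 at day 10, with members on both sides of 0. Ankrd1 (-2.46), Csrp3 (-2.29), Tbx20 (-1.39) and Hopx (-1.37) were at least 2-fold lower, Mef2c differed by -0.87 and Tbx5 by -0.37, whereas Gata4 (0.28), Hand2 (0.43) and Gata6 (0.68) lay above 0 and Tbx18, an epicardial factor, was higher by 2.10. Calcium handling and ion channel genes had a median of -0.18 with 7 of 20 lower, led by Kcnj5 (-2.01) and Cacna1c (-1.91), and the median was -0.76 with members past the filter only. Early cardiac mesoderm genes had a median of -0.13 at percentile 2.60, just inside the limit of 2.5, and lay below it with a floor of 200, the mean of all probes, members past the filter only, scaling to the 75th percentile and the values as deposited. The last pair of settings differs, once centred on the median of all genes, mainly through the floor, and so is not separate evidence. Primitive streak genes had a median of -0.14, inside the range, but lay below it as deposited (-0.45) and with scaling to the 75th percentile (-0.30), and Mesp1 was at the floor in both arrays.

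Liver-type endoderm genes showed the lowest list median at day 10, -1.73, with 13 of 18 at least 2-fold lower, including Apob (-3.70), Apom (-3.49), Ttr (-3.44), transthyretin, and Rbp4 (-3.41). Lrp2 stood against them at 2.51. Definitive endoderm genes had a median of -0.79, led by Spink1 (-5.17), and epithelial genes -0.90, with Cldn6 at -2.87. Epicardium genes were higher as a group (median 1.0, 7 of 12 at least 2-fold higher), led by Sema3d (2.72), Wt1 (2.61), Upk3b (2.39) and Aldh1a2 (2.38). Hox genes were again higher (median 0.66, 11 of 22), led by Hoxa10 (4.25), Hoxa7 (3.38) and Hoxa9 (3.34), with Hoxb6 at -0.71. Fibroblast and matrix genes (0.03), endothelial genes (-0.10), blood genes (-0.13), smooth muscle genes (0.10) and neural genes (0.02) lay inside the random range. Endothelial genes lay below it with members past the filter only (-0.18), and as deposited and with scaling to the 75th percentile (-0.21 in both), blood genes below it as deposited (-0.29), and neural genes above it with members past the filter only (0.33).

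Hypoxia and glycolysis genes had a median of -0.64 at day 10, with Egln3 (-1.73), Bnip3 (-1.69), Slc2a3 (-1.49) and Vegfa (-1.22) lower and Tpi1, triosephosphate isomerase, higher by 3.26. The lists of EMT regulators (-0.29), unfolded protein response (-0.28), p53 targets (-0.27), Notch (-0.25), FGF (-0.24) and BMP (-0.19) pathways and oxidative phosphorylation (-0.11) also lay below the random range, but oxidative phosphorylation came inside it with loess centring. Notch came inside with members past the filter only (-0.25), and as deposited and with scaling to the 75th percentile (-0.32 in both). Trophoblast genes had a median of 0.26, which lay inside the range with loess centring (0.015), with a floor of 200 (0.049), and as deposited and with scaling to the 75th percentile (0.021 in both). Outside the lists, Hoxa11os (4.91), Angptl7 (4.46), Cntn6 (3.33), Hs3st2 (3.22) and Mapt (3.05) were among the 10 highest ranked genes. The imprinted genes Nnat (-4.57, other probe -3.95), H19 (-4.54) and Plagl1 (-3.51), with Tdo2 (-3.73), Tff3 (-3.68) and Clic6 (-3.50), were among the 10 lowest, as were Spink1 and Apob. In all, 272 genes were at least 2-fold higher and 393 lower among 10888, and 15 lists lay below and 3 above the random range. Without normalization between arrays, 1134 genes were higher and 182 lower, with the median of all genes at 0.53.

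**Figure D3:**
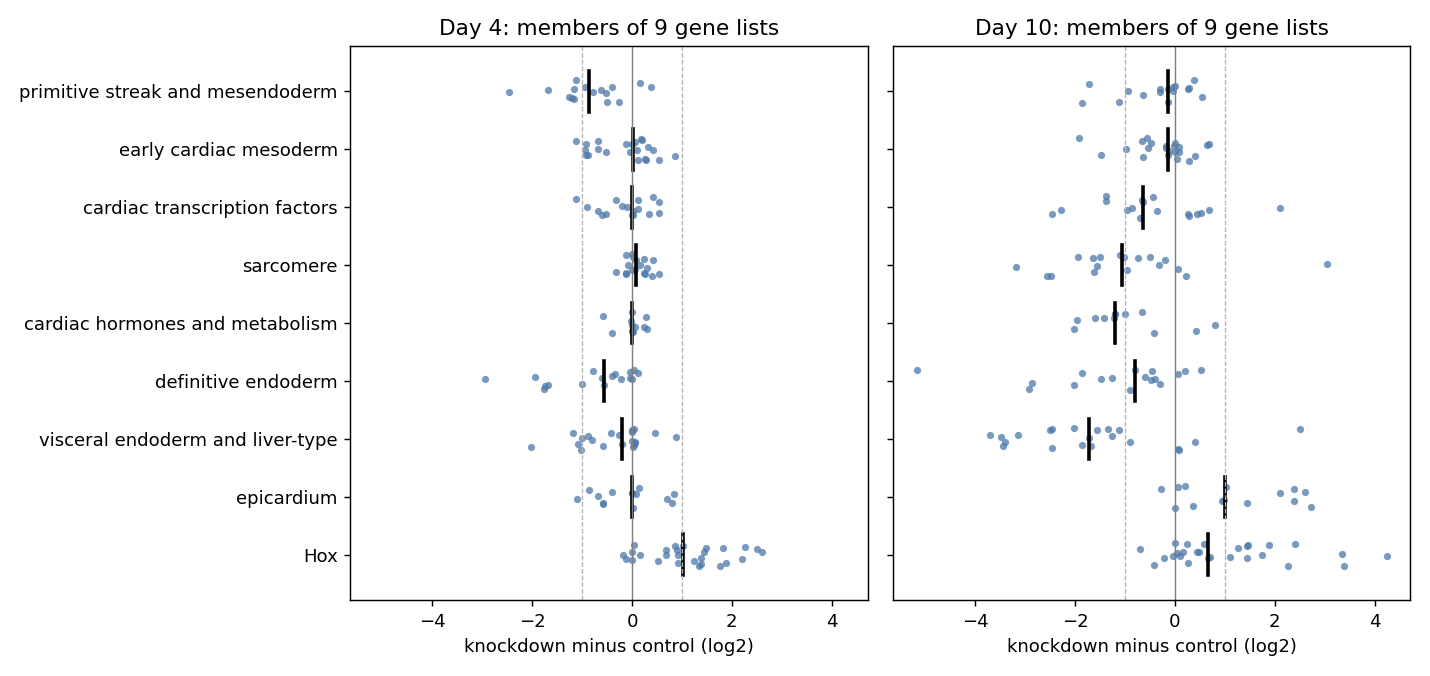
Log2 difference, knockdown minus control (horizontal axis), of every measured member of 9 gene lists at day 4 and day 10; each point is 1 gene, the black bar is the list median and dashed lines mark 2-fold differences. The primitive streak median lies at -0.86 at day 4 and -0.14 at day 10, the sarcomere median at 0.07 and -1.06, and the epicardium median at 1.0 at day 10.

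**Figure D4:**
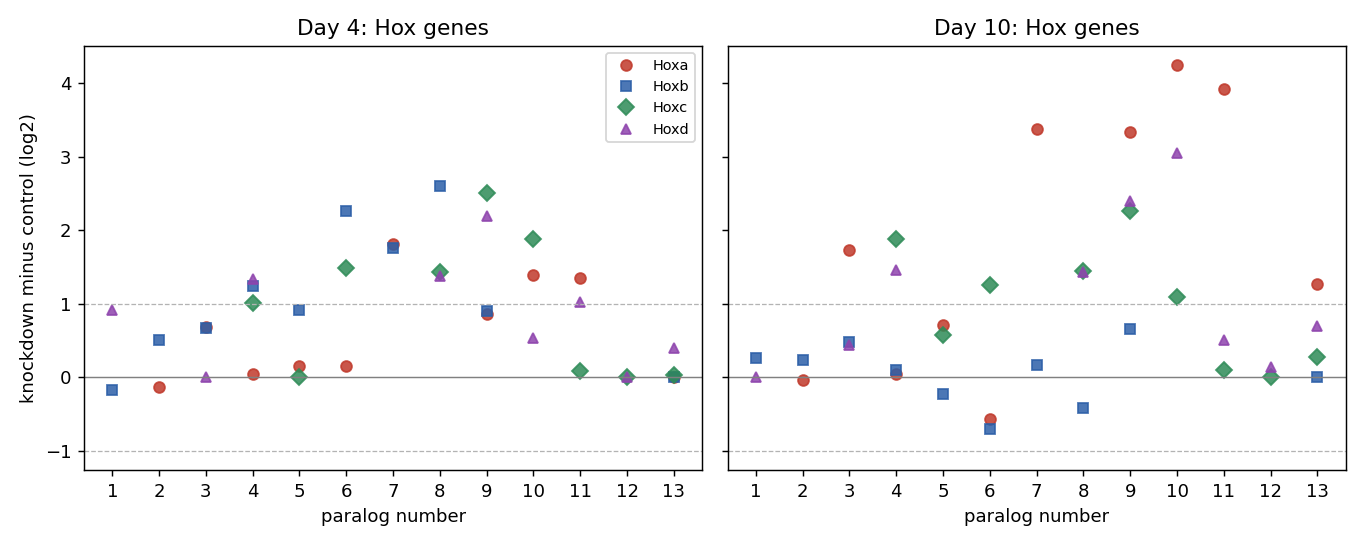
Log2 difference, knockdown minus control (vertical axis), of each measured Hox gene against its paralog number at day 4 and day 10, with a marker for each of the 4 clusters. Paralogs 6 to 11 had medians of 1.42 at day 4 and 1.35 at day 10, and those of paralogs 1 to 5 were 0.60 and 0.36.

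The time courses of both lines were compared on arrays that they do not share. Across 11737 genes, the difference between day 10 and day 4 in knockdown cells had a Pearson r of 0.904 with that in control cells, and the ratio of their SDs was 0.977. The knockdown differences at day 4 and at day 10 were only loosely related, with an r of 0.107 across the same genes, which are not independent replicates. Probe error limits how high that r could be. Even probes of the same gene had an r of only 0.41 for the day 4 difference and 0.69 for the day 10 difference. For overlaps a gene was kept if any of these 4 arrays passed the filter, so the counts differ from those above. They were 94 higher and 176 lower at day 4, and 285 and 404 at day 10. Genes at least 2-fold higher at both days numbered 25, against 2.28 for independent lists, among them 11 Hox genes with Tbx4, Pitx1, Osr1 and Lhx2. Of the Hox genes, Hoxa11 lay below the filter in both day 4 arrays. Genes lower at both days numbered 30, against 6.06, among them Foxa1, Foxa2, Afp, Apob, Ttr, Tdgf1, Nnat and H19. Genes lower at day 4 and higher at day 10 numbered 11, against 4.27, and those with the opposite order 3, against 3.24.

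Genes that separate stages in control cells were then followed in the knockdown on arrays not used to choose them. The 2676 genes higher in control day 10 than in ESCs had a median knockdown difference of 0.05 at day 4, and the 2608 lower genes -0.03. The 1447 genes higher in control day 4 than in ESCs had a median of 0.10 at day 10, and the 1574 lower genes -0.06. All 4 medians lay outside the central 95% of random gene sets, on the side of the control difference, and the last was -0.21 as deposited. With sets this large that range is narrow, so a small shift is enough to lie outside it. All 4 medians were small in size. The between-probe SDs describe a single probe and are not the error of such a median. Of the higher genes, 1.57% were at least 2-fold higher and 1.53% lower in the knockdown at day 4, and 4.35% and 4.15% at day 10. Of the lower genes, the shares were 0.69% and 2.42% at day 4, and 4.13% and 7.69% at day 10.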

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

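All tests in this part were chosen after the result was seen. Knockdown differences with opposite directions at day 4 and day 10 were picked out where both lay past their threshold, for the gene lists and for those genes that the naming rule covers and that passed the filter on each day. With 1 array per group none of these differences between days was tested. The median of the hypoxia and glycolysis list went from 0.29 at day 4 to -0.64 at day 10, a difference of -0.94. The median of the FGF pathway list went from 0.13 to -0.24, a difference of -0.37. Fgf5, a growth factor of the primed epiblast, went from -2.91 to 2.56, a difference of 5.47. Sema3d, a semaphorin of the epicardium list, went from -1.10 to 2.72, a difference of 3.82, but its other probe gave 0.06 at day 4. Stmn2, a neuronal stathmin, went from -1.18 to 1.68, a difference of 2.85. These genes are a selection: across 11737 genes, 11 were at least 2-fold lower at day 4 and higher at day 10, and 3 went the other way. Outside the naming rule were, for example, Gfra3 (-1.34 and 2.36) and Pcdh19 (-1.53 and 1.64), chosen after their values were seen. Probes unnamed here and past the filter also held 2-fold differences: 49 at day 4 (17 higher, 32 lower) and 98 at day 10 (37 higher, 61 lower).

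Hox genes were higher in the knockdown arrays at both days, with list medians of 1.01 and 0.66, but at day 10 the Hoxb genes of paralogs 6 to 9 had a median of -0.12. Under 3 other scalings the lowest Hox list median over both days was 0.68, at percentile 100 of random lists. These values cannot test a scale factor common to an array, which cancels once differences are centred on all genes. Loess centring, among the 3, removes a trend with intensity, and the Hox list stayed above the random range under it. The remaining settings differ mainly through the floor and are not separate evidence. An extra copy of wide regions around the 4 clusters was argued against. There, 3 copies in place of 2 would add 0.58 on the log2 scale, and the highest median of flanking genes was 0.098. The flanking genes were up to 50 on each side of a cluster, so a gain confined to a cluster or its near flanks was not tested. The knockdown itself, a difference between the cell lines that is unrelated to Linc1405 and a difference between cultures all stay open, untested, because each line and day had 1 array.

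Cardiac contraction genes were lower in the knockdown array at day 10 while Tnnt2 was higher by 3.05. A smaller share of cardiomyocytes would lower genes specific to them alike. Apart from Tnnt2, 18 cardiac genes were at least 8-fold higher at day 10 than at day 4 in the mean of both lines. All 18 were below 0, from Acta1 (-3.19) to Kcnj2 (-0.21), with a median of -1.30. They came from lists whose medians were already seen to be lower in these arrays, so their shared direction is not separate support. The SD of the 18 genes was 0.81, above a limit of 0.54, derived from the between-probe SD, that had been set against a uniform loss. That limit was set aside because probe error alone cannot judge the SD. All genes past the filter had an SD of 0.55 between these cultures, just above the same limit. A uniform loss and gene-specific differences therefore cannot be told apart. A fault of the Tnnt2 spot and a true rise cannot be told apart, because Tnnt2 had 1 probe. A smaller share of cardiomyocytes, with the knockdown or a difference between lines or cultures behind it, stays open.

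The imprinted genes H19, Nnat and Plagl1 were lower in the knockdown arrays at day 4 (-2.16, -1.53 and -0.97) and at day 10 (-4.54, -4.57 and -3.51). For imprint differences at many loci between the lines, the median absolute difference of 40 other imprinted genes at day 10 was 0.30, at percentile 97.41 of matched random lists, just inside the upper limit set for it, while at day 4 it was 0.24 at percentile 99.97. For a smaller share of endoderm cells, the median of these genes at day 10 was -4.54, beyond the median of 37 endoderm markers (-1.48) but not beyond the lowest of them (-5.17). That lowest marker was Spink1 alone, and the next lowest was Apob (-3.70). H19 and Nnat thus lay beyond every marker but Spink1, whereas Plagl1 did not lie beyond Apob. Both explanations therefore stay open and cannot be told apart by these values. No direct measure of imprinting was used here, and an effect of the knockdown was not tested.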

How the results depend on the processing

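No paired analysis was possible because the groups compared share only 1 replicate number; this concerns pairing by replicate number alone. Pairing the lines by day, in an additive fit over the 4 arrays of days 4 and 10 that takes the knockdown difference as equal on both days, was possible but was not run. Floors of 50 and 200 and scaling to the 75th percentile were chosen after seeing the data. Of the list medians under the alternatives, 963 stayed within the between-probe SD with the same call, 67 moved and 1 reversed. Only a median outside the random range could count as reversed, and a change of sign inside it did not. The between-probe SD applies to a single probe and exceeds many of the knockdown list medians. Such a median could vanish without leaving that limit, so for these lists mainly the call was checked. Of the counts, 50 stayed within 1.5 times and 22 moved. Of single-gene values 5140 were the same, 176 moved and 0 reversed. Many of these values could hardly move, so the number that stayed the same is no measure of stability. The mean of all probes leaves a gene with 1 probe as it was, and another floor acts only on dim values. Only a gene at least 2-fold apart in the main setting could count as reversed, so smaller differences could change sign without being counted. Signal over background limits dim genes, since about 19% of the probes of each array lay at the floor. Where no construction is named, the cause was not tested.

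Fewer genes passed stricter limits. With a 75th percentile filter the higher and lower counts were 24 and 33 for knockdown day 4, 116 and 181 for knockdown day 10, 677 and 761 for control day 4 against ESCs, and 1222 and 1274 for control day 10 against day 4. With a 4-fold threshold they were 12 and 18, 63 and 60, 450 and 658, and 967 and 462 in the same order. Without a filter, 239 genes were lower at knockdown day 4.

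As deposited, without normalization between arrays, 1134 genes were higher and 182 lower at knockdown day 10, 2244 were higher at control day 4, and 1164 were higher and 5233 lower at control day 10. Unlike the list medians that follow, these counts were not centred, so they carry the difference in scale between the arrays. At knockdown day 4 the epiblast (-0.20) and fibroblast and matrix (-0.12) lists then lay outside the random range. At knockdown day 10 so did pluripotency (-0.26), primitive streak (-0.45), early cardiac mesoderm (-0.19), endothelial (-0.21) and blood (-0.29), while Notch (-0.32) and trophoblast (0.021) came inside. Calcium handling (-0.53) and liver-type endoderm (-2.08) medians moved and stayed below the range, and the germ cell median turned from 0.17 to -0.30, inside the range in both settings. Neural genes (-0.36) at control day 4, and smooth muscle (0.88) and BMP (-0.54) at control day 10, came inside. The epiblast, calcium handling, neural and smooth muscle values of this setting are the median of all genes with its sign turned, since the median member lay at the floor in both arrays, so they give no size of a difference. Genes lower in control day 4 than in ESCs had a knockdown difference of -0.21 at day 10, against -0.06.

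With only members past the 50th percentile, so with fewer genes, the paraxial median at knockdown day 4 turned from -0.10 to 0.0023 and came inside. Epiblast (-0.46), sarcomere (0.20), calcium handling (-0.14), smooth muscle (0.20) and Notch (-0.22) lists went outside, and Hox stood at 1.34. At knockdown day 10 pluripotency (-0.19), early cardiac mesoderm (-0.16), neural (0.33) and endothelial (-0.18) went outside and Notch (-0.25) inside, with sarcomere at -1.496, calcium handling at -0.76 and trophoblast at 0.77. At control day 4 cardiac hormones (-1.85), Notch (-1.26), Hox (1.11) and trophoblast (1.49) went outside and neural (-0.34) inside, with cardiac transcription factors at 2.80 and Wnt at 1.90. At control day 10 epithelial (-0.79) and Notch (1.28) went outside and paraxial (-0.79) inside, with cardiac hormones at 3.05 and epicardium at 4.17.

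With loess centring, sarcomere (0.12) at knockdown day 4, epiblast (0.19) at knockdown day 10 and Hox (0.23) at control day 4 went outside, and oxidative phosphorylation (-0.11) and trophoblast (0.015) at knockdown day 10 came inside. Scaling to the 75th percentile differs from the values as deposited, once both are centred, mainly through the floor, so the settings are not separate evidence. With it, paraxial (-0.065) and trophoblast (0.038) at knockdown day 4 came inside, as did Notch (-0.32) and trophoblast (0.021) at knockdown day 10, neural (-0.32) at control day 4 and BMP (-0.54) at control day 10. Under it primitive streak (-0.30), early cardiac mesoderm (-0.18) and endothelial (-0.21) at knockdown day 10 went outside, and liver-type endoderm stood at -2.08.

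With a floor of 50, paraxial stood at -0.32 at knockdown day 4 and Hox (0.73) went outside at control day 4. With a floor of 200, liver-type endoderm (0.00) at knockdown day 4, trophoblast (0.049) at knockdown day 10, neural (-0.035) at control day 4 and Wnt (-0.32) at control day 10 came inside. Early cardiac mesoderm (-0.13) at knockdown day 10 went outside, and cardiac hormones stood at 2.46 at control day 10. With the mean of all probes, skeletal muscle (0.20) at knockdown day 4 and early cardiac mesoderm (-0.13) at knockdown day 10 went outside, and neural (-0.48) at control day 10 came inside.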

Other observations

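Genes of the mesothelium, the cell layer that lines body cavities and covers the heart, were higher as a group in the knockdown array at day 10, on a list of 14 genes chosen after seeing the data. Their median was 2.05, with 11 of 13 members past the filter at least 2-fold higher, among them Muc16 (2.29), Rspo1 (2.28), Myrf (2.14), Krt7 (2.09), Lrrn4 (2.07) and Efemp1 (2.03). Krt19 (0.05) and Bnc1 (0.95) stayed under 2-fold. At day 4 the median was -0.04 with 0 members 2-fold higher. Wt1, Upk3b, Upk1b, Bnc1, Krt19 and Msln also belong to the epicardium list, and Krt7 to the trophoblast list, so these lists are not independent.

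Other imprinted genes, on a list of 43 chosen after seeing the data, went both ways in the knockdown arrays. Dlk1, a Notch-related growth regulator, was higher by 1.79 at day 4 and differed by 0.26 at day 10. Peg10 differed by 0.85 and 1.34, Phlda2 by 0.15 and 1.45, and Ascl2, a trophoblast factor, by 0.16 and 1.32. Asb4 differed by -1.92 and -1.11, Calcr by -1.96 and -0.49, and Dio3 by 0.34 and -1.46. Igf2, which shares an imprinting control region with H19, differed by 0.39 and 0.08. The list median was 0.16 at day 4, at percentile 100 of matched random lists, and -0.03 at day 10, at percentile 13.5.

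Some genes stood apart in a single array of differentiated cells by at least 16-fold from every other array, among them 1520401A03Rik, at a log2 intensity of 17.26 in knockdown day 4 and between 6.64 and 8.40 elsewhere. Cep57l1 was at 7.85 in knockdown day 4 and between 12.56 and 13.57 elsewhere. Angptl7 and Hoxa11os stood highest in knockdown day 10, at 14.49 and 11.58, and Nnat in control day 10, at 13.83. Further genes outside that rule were picked after their values were seen. Tpi1, a glycolytic enzyme, was at 15.15 in control day 10 and at 17.77 or more elsewhere, so its difference of 3.26 rests on a low control value. Prdm14, a factor of the pluripotent and germ cell states, was at 13.18 in knockdown day 10 and at the floor in control day 10. Mrpl36 was at the floor in ESCs and knockdown day 10 and at 14.38 or more elsewhere, and Top2b was at the floor in ESCs and both day 4 arrays and at 14.41 and 14.69 at day 10. Each of these levels comes from the brightest probe of the gene on 1 array, and no explanation was tested.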
